A study of Mus musculus with 24 samples.

How the data were processed

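RNA from brown adipose tissue (BAT) and white adipose tissue (WAT) of male C57BL/6J mice had been hybridised to Illumina mouse whole-genome expression arrays. The labels give 24 arrays in 6 groups of 4, 1 group for each of 3 diets in each of 2 tissues. The diets were a low-fat diet, a high-fat diet (HFD) with corn oil and a high-fat diet enriched in eicosapentaenoic and docosahexaenoic acid (EPA/DHA). Per the labels, the mice of each diet had been picked to represent their group in body weight and in plasma triglyceride and cholesterol. The WAT depot is not stated, and the extraction text names skeletal muscle where the tissue labels name adipose tissue. The labels do not say whether BAT and WAT arrays with the same replicate number came from 1 mouse.

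The deposited values are log2 expression per probe, made by the authors with lumi 2.18.0 and quantile normalised over all 24 arrays. The labels do not state whether the scale is a plain log2 or a log2-like variance-stabilised one, so differences near the floor can be smaller than on a plain log2 scale. Values ran from 6.95 to 14.79, with a floor near 7. The sorted values of any 2 arrays differed by at most 0.0069, so a change in total signal between arrays could not be seen. Detection calls were not used here, and precision was limited by the number of arrays. The table held 45281 probes. A gene symbol was given for 34885 of them, and 34818 of these matched a RefSeq gene (names of assembly GRCm38.p6) by gene ID or accession. Several symbols were given for 18 probes, and 10378 stayed unnamed here. Each of the 19053 named genes was represented by its probe with the highest mean over the 24 arrays. Probe sequences were not aligned, so members of families with near-identical copies, such as the Mup, Ces1 and Ear genes with Rnase2a, are uncertain.

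Diets were compared within each tissue by limma 3.58.1 in R 4.3.3, with 1 mean per diet, the 12 arrays of the tissue sharing 1 estimate of the spread. Probes were kept when their mean over the tissue's arrays lay above the 40th percentile (7.11 in both tissues), which left 27168 probes in each. The kept probes represented 13349 genes in WAT and 13400 in BAT. The moderated test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over the kept probes, and the threshold was an adjusted p of 0.05. The difference of a diet effect between tissues was tested as an interaction over all 24 arrays and the 29493 probes kept in either tissue. The same fit compared WAT with BAT on the low-fat diet. Differences are given in log2 units with their standard error.

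The comparisons, the alternatives not described as added, 31 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered 19 pathways and 12 cell types or tissues that an adipose sample can hold, with 602 members, 549 of which had a named probe. The macrophage gene Cd68 had none and is not reported. Lists were tested in 186 tests by camera with its preset correlation of 0.01, which asks whether a list's genes shifted relative to all other genes. Camera with an estimated correlation and fry were run beside it. Named genes are, for each diet comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list past the threshold. Where fewer than 10 genes passed, the 5 smallest p-values are named. Lep, Adipoq, Ucp1, Fasn, Scd1 and Mest are given throughout. For each interaction the 5 smallest adjusted p-values are named, and for WAT against BAT the 5 largest differences each way. Some list members are also named that passed only when adjusted over their list alone. Other genes named outside this rule are said to be. Marker scores are the mean log2 value of a list's kept members in 1 array, compared by exact two-sided permutation tests.

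The pipeline was tested on simulated data of the same size, with 200 changed probes in each of 20 simulations. At a log2 change of 0.5, the share recovered was 85.6% for a WAT comparison, 77.2% for a BAT comparison and 73.4% for an interaction. At a log2 change of 1 these shares were 97.6%, 95.8% and 93.3%. At a log2 change of 2 they were 99.1%, 99.3% and 99.4%. Over all sizes, 5.3%, 5.7% and 4.7% of the calls were false. The changed probes were drawn at random from the kept ones, whose median residual SD was 0.055 in WAT and 0.085 in BAT. The recovered shares therefore do not hold for probes with a larger spread, such as that of Lep in BAT. For the list test, 1 list of 20 genes shifted by 0.3 was recovered in 100% of the WAT simulations, with 4.8% false calls. All simulated genes varied independently and the simulated lists were random. The 4.8% is therefore no false-call rate for real lists, whose genes can move together.

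The alternatives were no filter, a filter at the 60th percentile, renewed quantile normalisation, median centring, a trended and robust prior, array weights, 1 fit over all 24 arrays (for the tissue and interaction comparisons, a random block), a fixed replicate block, 1 probe per gene and leaving out each array in turn. For the tissue and interaction comparisons, both blocks were diet and replicate number together. For the lists, the mean over all probes of a gene was also tried. Added after the data were seen were fits without 2 WAT arrays with raised Ucp1, without the BAT array farthest from the others and without these 3 arrays together, and fits with the skeletal muscle score (BAT) or the liver score (WAT) as a covariate.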

Results

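Gene expression was measured in BAT and WAT of mice fed a low-fat diet, a corn-oil HFD or an EPA/DHA HFD, with 4 arrays per tissue and diet. The series title names adiposity-related genes in the 2 adipose tissues under an EPA/DHA-enriched diet, and the comparisons below follow that question. All values are log2 expression, differences carry ± their standard error, and each group held 4 arrays. Mean correlations of an array with the other arrays of its tissue ran from 0.969 in BAT low-fat replicate 2 to 0.992. No pair of arrays was a duplicate, the highest pairwise correlation being 0.9958. As these are arrays, precision was limited by their number. The highest value was 14.79, and Lep (13.2 to 14.7) and Adipoq (13.99 to 14.42) in WAT, Ucp1 (13.6 to 14.4), Cidea (13.82 to 14.41) and Cox7a1 in BAT, Mup2 in WAT (up to 14.6) and Scd1 in both tissues lay close to it. Differences of these probes can be understated, and a result that did not pass there does not show that nothing changed.

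On the low-fat diet the 2 tissues differed as brown and white fat do. Ucp1, the uncoupling protein of brown fat, was at 14.16 ± 0.05 in BAT and 7.35 ± 0.45 in WAT (SD, n = 4), a WAT minus BAT difference of -6.81 ± 0.57. Other large differences towards BAT were those of Fabp3 (-5.98 ± 0.39), Cox7a1 (-5.76 ± 0.42), Cidea (-5.61 ± 0.52) and Acot11 (-5.26 ± 0.27). In WAT Ucp1, Fabp3 (7.18 ± 0.14, SD) and Acot11 (7.26 ± 0.15, SD) lay near the floor of about 7, and Ucp1, Cidea and Cox7a1 in BAT near the top, so these 5 differences are lower bounds. Leptin (Lep), the hormone of white fat, was at least 5.02 ± 0.38 higher in WAT. Adipoq (0.83 ± 0.09) and Mest (2.47 ± 0.37) were higher in WAT, Fasn was lower (-1.47 ± 0.20), and Scd1 did not pass (-0.27 ± 0.12, adjusted p = 0.0983). Of the other large differences towards WAT, all were in genes with high expression in liver, Mup2 (at least 5.69 ± 0.74), Mup3 (5.06 ± 0.68), Apoa2 (4.66 ± 0.76) and Ttr (4.60 ± 0.68). In all, limma called 11050 probes, 5526 higher and 5524 lower in WAT, covering 6236 genes. The 13 genes named here as past the threshold passed without any 1 of the 8 low-fat arrays.

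WAT of mice on the corn-oil HFD differed from low-fat WAT in 517 genes, 274 higher and 243 lower. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, rose by 2.56 ± 0.20 (adjusted p = 9.8e-04). It went from 7.92 ± 0.18 on the low-fat diet to 10.48 ± 0.41 on corn oil (SD). Tph2, an enzyme of serotonin synthesis, rose by 2.69 ± 0.33, and Rnase2a, of the eosinophil-associated ribonuclease family, by 2.03 ± 0.26. The H2-DMa and H2-DMb1 genes, which load peptides onto MHC class II molecules, rose by 0.70 ± 0.07 and 0.86 ± 0.12. Ivd, an enzyme of leucine breakdown, fell by 0.74 ± 0.10 (adjusted p = 0.00579), and Gsta4, a glutathione transferase, fell by 0.56 ± 0.06 (adjusted p = 0.00264).

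Among the other large rises were the chemokine gene Ccl8 (1.83 ± 0.35), the choline transporter Slc5a7 (1.34 ± 0.27), Lipf (1.34 ± 0.23), the proteoglycan gene Gpc1 (1.33 ± 0.19) and Lbp, which encodes the lipopolysaccharide-binding protein (1.32 ± 0.27). Among the large falls were those of the protease inhibitor Slpi (-1.46 ± 0.34), Ces1f (-1.45 ± 0.30), Net1 (-1.37 ± 0.22), the glutamate transporter Slc1a3 (-1.26 ± 0.26), Nnat (-1.20 ± 0.19), the secreted glutathione peroxidase Gpx3 (-1.16 ± 0.26), Slc43a1 (-1.09 ± 0.18) and Vnn3 (-0.97 ± 0.20). Slpi stood far apart in low-fat replicate 1, at 12.68 against 11.16 to 11.33 in the other 3 arrays. Its difference without that array was -1.10, and it lost its call without any 1 array. Neither Lep (0.70 ± 0.28, adjusted p = 0.233) nor Adipoq (-0.08 ± 0.09, adjusted p = 0.735) passed. The same held for Ucp1 (0.35 ± 0.76), Fasn (-0.17 ± 0.22) and Scd1 (0.20 ± 0.12). Mest, a gene tied to fat mass expansion, was 1.44 ± 0.50 higher at its brightest probe, which did not pass (adjusted p = 0.166). Of 2 dimmer Mest probes, looked at after their values were seen, 1 passed at 1.18 ± 0.28 (adjusted p = 0.0491) and the other, at 1.61 ± 0.41, did not (adjusted p = 0.0662).

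Of the 16 measured MHC class II and antigen presentation genes, 4 rose, none fell and 12 did not pass, with H2-DMb1, H2-DMa, H2-Eb1 (0.63 ± 0.14) and Cd74 (0.56 ± 0.12) the risers. Their mean was 0.30 higher (camera adjusted p = 2.1e-04; adjusted p = 0.452 with an estimated correlation), and 7 rose when adjusted over the list alone. Of the 21 inflammatory cytokine and chemokine genes, Ccl8 and Ccl7 (1.25 ± 0.27) rose and 19 did not pass, 6 rising when adjusted over the list alone. That list was called (adjusted p = 0.0196; adjusted p = 0.688 with an estimated correlation) but not without low-fat replicate 2 (adjusted p = 0.114). Col5a1 (0.42 ± 0.09) and Timp1 (0.81 ± 0.19) rose among 25 extracellular matrix genes, 4 when adjusted over the list alone, with a list mean of 0.19 (adjusted p = 0.0014; adjusted p = 0.452 with an estimated correlation). No single macrophage marker passed among 20, although limma gave 11 with an unadjusted p under 0.05. Their mean was 0.49 higher (adjusted p = 7.0e-04; adjusted p = 0.672 with an estimated correlation), with 8 passing when adjusted over the list alone. The macrophage score was 9.51 ± 0.19 on corn oil and 9.02 ± 0.10 on the low-fat diet (SD). Its exact permutation p was 0.0286, the smallest possible here, and 0.294 when adjusted over 72 score tests. Whether the score moved with the immune and matrix lists from array to array was not tested. The mesothelial score differed by -0.169 and the mast cell score by -0.263, with the same exact p and adjusted p.

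Of 14 cell cycle genes, all with positive differences, 5 rose and 9 did not pass, and the list mean was 0.20 (adjusted p = 1.0e-10; adjusted p = 0.239 with an estimated correlation). Mcm5 (0.46 ± 0.08), Birc5 (0.26 ± 0.05), Bub1b (0.25 ± 0.05) and Cdc20 (0.21 ± 0.03) were among those that rose, and 13 rose when adjusted over the list alone. The brightest Cdc20 probe averaged 7.25, near the floor, and the 3 dimmer ones did not pass, at 0.066, 0.055 and -0.024 (adjusted p = 0.332, 0.558 and 0.784). Of 18 cholesterol synthesis genes, Hsd17b7 (0.60 ± 0.10) and Cyp51 (0.46 ± 0.11) rose, 16 did not pass, and 10 rose when adjusted over the list alone. Cyp51 lost its call without any 1 array and Hsd17b7 kept it. The list mean was 0.28 (adjusted p = 1.4e-06; adjusted p = 0.407 with an estimated correlation).

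Of 16 genes of branched-chain amino acid breakdown 5 fell, including Ivd, Bcat2 (-0.69 ± 0.15), Bckdha (-0.49 ± 0.08) and Pccb (-0.40 ± 0.09), and none rose. The mean was -0.36 (adjusted p = 5.1e-08; adjusted p = 0.239 with an estimated correlation), and 11 fell when adjusted over the list alone. Cebpa (-0.48 ± 0.07) and Insr (-0.47 ± 0.11) fell among 18 insulin signalling and adipogenic genes, and the same 2 genes made up the count adjusted over the list alone. Cebpa kept its call without any 1 array, while Insr lost it each time. That list had a mean of -0.23 (adjusted p = 0.00198; adjusted p = 0.239 with an estimated correlation). The oxidative phosphorylation list had a mean of -0.11 (adjusted p = 0.0032; adjusted p = 0.734 with an estimated correlation). Of its 33 genes Uqcrc2 fell (-0.34 ± 0.08) and 4 fell when adjusted over the list alone. Lower means were also called for 14 circadian clock genes at -0.27 (adjusted p = 0.0122; adjusted p = 0.281 with an estimated correlation) and 9 mast cell markers at -0.26 (adjusted p = 0.00251; adjusted p = 0.417 with an estimated correlation). Nr1d1 (-0.49 ± 0.11) and Mcpt4 (-0.53 ± 0.10) fell in these 2 lists, where 2 and 5 members fell when adjusted over the list alone.

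In lists that were not called as a whole, Thrsp, a lipogenic regulator, fell by 0.82 ± 0.14 (adjusted p = 0.015) and Pck1 by 0.84 ± 0.15. Hp (0.81 ± 0.16) and Sfrp5 (0.81 ± 0.17) rose among the adipokine and adiposity-associated genes, where Nnat fell. Ltc4s (0.69 ± 0.11) and Ephx1 (0.68 ± 0.12) rose among the eicosanoid genes, and Sod2 (0.29 ± 0.06) among the antioxidant genes. Pvalb (0.29 ± 0.05) and Ryr1 (0.15 ± 0.03), members of the skeletal muscle list, rose from low levels, while the dimmest Ryr1 probe gave -0.01 ± 0.02. The 20 lists not called, these included, had adjusted p-values from 0.0686 for heat shock and immediate early genes to 0.978. The liver score was 0.31 higher on corn oil (exact permutation p = 0.714) and spread by more than 2 log2 units within each diet.

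By limma, 797 probes passed in this comparison, 406 higher and 391 lower, and 12.4% of the genes did not overlap between the groups against 2.86% by chance. Here and below, the 2.86% is the mean over all groupings of the arrays. Its spread over the groupings was not computed, and genes can move together. The count fell to 330 without low-fat replicate 1, 266 without low-fat replicate 4, and 423, 440, 426 and 335 without corn-oil replicates 1, 2, 3 and 4. Without the 2 WAT arrays with raised Ucp1 it was 380. Of the 48 named genes past the threshold, 19 passed without any 1 array, among them Ubd, Tph2, Rnase2a, H2-DMa, H2-DMb1, Ivd, Gsta4 and Thrsp. Slpi, Cyp51, Insr, H2-Eb1, Nr1d1 and Uqcrc2 passed in none of the 8 fits, and Bcat2, Ccl7, Cd74, Ces1f, Col5a1, Gpx3, Pccb, Sod2 and Timp1 in 1. With the liver score as a covariate 9 of the 48 lost their call, among them Ccl7, Cyp51, Insr and Timp1. Their differences were then 1.236, 0.462, -0.46 and 0.798, close to those without the covariate. The calls of 26, 13, 11 and 26 named genes ended without low-fat replicates 1 to 4, and of 22, 21, 21 and 25 without corn-oil replicates 1 to 4, with no change of sign.

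**Figure D1:**
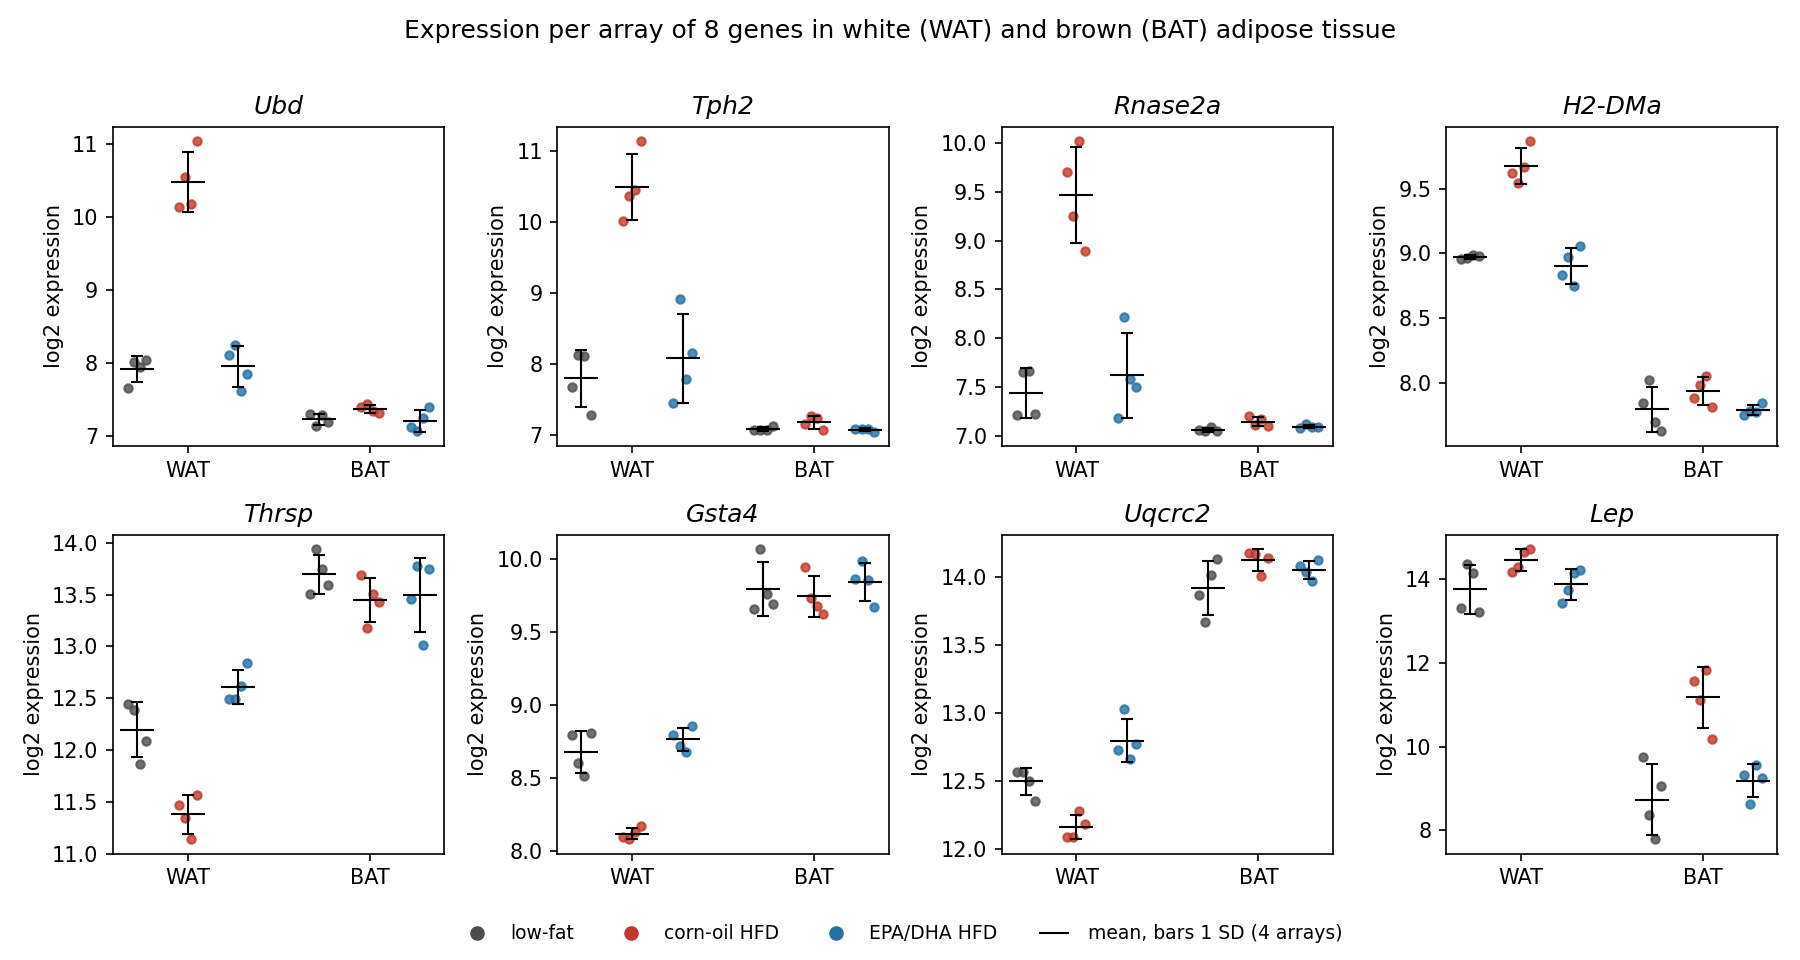
Log2 expression per array of 8 genes in WAT and BAT on the 3 diets, with 1 point per array, the mean and 1 SD. In WAT the corn-oil arrays of Ubd, Tph2, Rnase2a and H2-DMa lie above the arrays of both other diets, those of Thrsp, Gsta4 and Uqcrc2 lie below them, and Lep in BAT is highest on corn oil without passing the test.

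WAT on the EPA/DHA HFD differed from WAT on the corn-oil HFD in 313 genes, 157 higher and 156 lower. Ubd fell by 2.52 ± 0.20 (adjusted p = 9.2e-04), Tph2 fell by 2.41 ± 0.33 and Rnase2a fell by 1.85 ± 0.26. Thrsp rose by 1.23 ± 0.14 (adjusted p = 0.00241), from 11.38 ± 0.18 on corn oil to 12.61 ± 0.16 on EPA/DHA (SD). Of the measured genes, 7 of 33 for oxidative phosphorylation, 2 of 24 for fatty acid oxidation and 5 of 16 for branched-chain amino acid breakdown rose, and 5 of 16 for MHC class II fell. None of these 4 list calls held with an estimated correlation (adjusted p = 0.278, 0.317, 0.239 and 0.321).

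The other large falls were those of Lbp (-1.50 ± 0.27), Ear3, a further eosinophil-associated ribonuclease (-1.38 ± 0.12), the secreted Wnt antagonist Sfrp5 (-1.12 ± 0.17), the collagen gene Col16a1 (-1.09 ± 0.10) and Lipf (-1.09 ± 0.23). The other large rises were those of Ces1f (1.49 ± 0.30), the mitochondrial glycerol phosphate dehydrogenase Gpd2 (1.19 ± 0.19), Parm1 (1.12 ± 0.23), the pentose phosphate enzyme Tkt (1.09 ± 0.16), Sfxn1 (0.99 ± 0.10), Nat8l, which makes N-acetylaspartate (0.96 ± 0.13), and Eci3 (0.85 ± 0.16). Lep (-0.57 ± 0.28, adjusted p = 0.374), Adipoq (0.02 ± 0.09), Ucp1 (0.49 ± 0.76), Fasn (0.48 ± 0.22, adjusted p = 0.349) and Scd1 (-0.04 ± 0.12) did not pass. Mest had a difference of -1.78 ± 0.50 at its brightest probe and did not pass there (adjusted p = 0.105). Both dimmer Mest probes passed, at -1.97 ± 0.41 and -1.33 ± 0.28 (adjusted p = 0.0409 and 0.0408). They were looked at after their values were seen.

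All 33 measured oxidative phosphorylation genes had positive differences, with 7 past the threshold, 26 not, and 27 when adjusted over the list alone. Uqcrc2 (0.64 ± 0.08), Ndufa2 (0.38 ± 0.06), Atp5c1 (0.37 ± 0.07) and Cox4i1 (0.33 ± 0.05) were among the risers, and the mean was 0.32 (adjusted p = 1.4e-16; adjusted p = 0.278 with an estimated correlation). Branched-chain amino acid breakdown had 5 of 16 genes higher and none lower, with Bckdha (0.55 ± 0.08), Ivd (0.50 ± 0.10), Pccb (0.44 ± 0.09) and Pcca (0.40 ± 0.08) as examples. Its mean was 0.37 (adjusted p = 5.7e-10; adjusted p = 0.239 with an estimated correlation), and 13 rose when adjusted over the list alone. Eci1 (0.63 ± 0.12) and Acads (0.46 ± 0.10) rose among 24 fatty acid oxidation genes, 8 when adjusted over the list alone. With the liver covariate Eci1 and Acads were still higher, by 0.637 and 0.392, but lost their calls (adjusted p = 0.0605 and 0.072). The mean of the oxidation list was 0.30 (adjusted p = 1.1e-07, and adjusted p = 0.317 with an estimated correlation). Thrsp and the pyruvate carboxylase gene Pcx (0.58 ± 0.10) rose among 18 lipogenic genes, 7 when adjusted over the list alone, with a mean of 0.51 (adjusted p = 3.5e-05; adjusted p = 0.39 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, rose (0.50 ± 0.10) in the insulin signalling list, whose mean was 0.20 (adjusted p = 0.0057; adjusted p = 0.278 with an estimated correlation), 4 genes rising when adjusted over the list alone. Gsta4 (0.65 ± 0.06) and Prdx3 (0.42 ± 0.09) rose in the antioxidant list, mean 0.15 (adjusted p = 0.0141; adjusted p = 0.258 with an estimated correlation). Over that list alone 7 rose and 2 fell, and the list was not called without EPA/DHA replicate 1 (adjusted p = 0.0562).

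Among the 16 MHC class II and antigen presentation genes 5 fell, including Cd74 (-0.89 ± 0.12), H2-DMb1 (-0.89 ± 0.12), H2-Eb1 (-0.82 ± 0.14) and H2-DMa (-0.77 ± 0.07), and 7 fell when adjusted over the list alone. The list mean was -0.40 (adjusted p = 1.8e-07; adjusted p = 0.321 with an estimated correlation). Bub1b (-0.21 ± 0.05) fell among 14 cell cycle genes, 12 when adjusted over the list alone, with a mean of -0.15 (adjusted p = 1.6e-07; adjusted p = 0.281 with an estimated correlation). Col5a1 (-0.47 ± 0.09) fell among 25 matrix genes, 9 when adjusted over the list alone, mean -0.23 (adjusted p = 1.5e-05; adjusted p = 0.337 with an estimated correlation). Sfrp5 and Hp (-0.89 ± 0.16) fell in the adipokine and adiposity list of 20, where over the list alone 4 fell and 1 rose. Its mean was -0.34 (adjusted p = 0.00405; adjusted p = 0.459 with an estimated correlation). Lower means were also called for inflammatory genes at -0.24 (adjusted p = 0.00386; adjusted p = 0.594 with an estimated correlation) and endothelial markers at -0.18 (adjusted p = 0.00488; adjusted p = 0.337 with an estimated correlation). The macrophage list had a mean of -0.21 (adjusted p = 0.0292; adjusted p = 0.83 with an estimated correlation), and the endothelial score differed by -0.181 (exact p = 0.0286, 0.294 adjusted). The macrophage score did not separate these diets (9.30 ± 0.44 against 9.51 ± 0.19, SD; exact permutation p = 0.457). The macrophage list's call ended without corn-oil replicate 2 or 4 or EPA/DHA replicate 3 or 4, with adjusted p-values up to 0.469. No member of these 3 lists passed in limma or when adjusted over the list alone. Outside the called lists, Ephx1 fell by 0.98 ± 0.12, Asns rose by 0.84 ± 0.14, and Pvalb (-0.29 ± 0.05) and Ryr1 (-0.13 ± 0.03) fell. The 18 lists not called had adjusted p-values from 0.113 for triglyceride storage to 0.978, and the liver score differed by -0.80 (exact permutation p = 0.314).

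By limma 477 probes passed, 252 higher and 225 lower, and 10.2% of the genes did not overlap against 2.86% by chance. The count was 251, 254, 238 and 300 without corn-oil replicates 1, 2, 3 and 4, and 175 and 208 without EPA/DHA replicates 3 and 4. It was 299 without the 2 WAT arrays with raised Ucp1, and 300 with the liver score as a covariate. Of 41 named genes past the threshold, 21 passed without any 1 array, among them Ubd, Tph2, Rnase2a, Ear3, Thrsp, Tkt, Sfxn1, Uqcrc2, Cd74 and H2-DMa. Col5a1 and Prdx3 passed in none of the 8 fits, and Acads, Atp5c1, Bub1b, Ces1f, Eci1, Eci3, Ivd, Lipf, Pcca, Pccb and Ryr1 in 1. These 13, with Hp, Parm1 and Slc2a4, were the 16 that lost their call with the liver score as a covariate. Their differences kept their sign and stayed of similar size, as with Hp at -0.876, Parm1 at 1.147, Slc2a4 at 0.471, Ces1f at 1.566 and Acads at 0.392. The calls of 16, 17, 17 and 14 named genes ended without corn-oil replicates 1 to 4 and of 12, 11, 16 and 17 without EPA/DHA replicates 1 to 4, with no change of sign.

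The 2 comparisons share the corn-oil arrays, which alone makes them mirror each other. Across 13349 genes their differences correlated at -0.782, against -0.493 in simulated data without an effect. Genes are not independent replicates, whereas the simulated genes were drawn independently, so this gap alone does not show a reversal. Of the genes called in both, 112 were higher on corn oil than on low fat and lower on EPA/DHA than on corn oil, and 68 went the other way. With the corn-oil arrays split so that each comparison used its own pair, the correlation over the 6 splits ran from -0.604 to -0.300, with 20 to 29 shared opposite calls and none in the same direction. These were a minority of the 42 to 128 calls of the first and the 60 to 114 of the second comparison in these splits.

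WAT on the EPA/DHA HFD differed from low-fat WAT in 4 named genes. Of these, Mcrip2 (0.52 ± 0.07) and Qrsl1 (0.36 ± 0.05) rose and Rprml (-0.57 ± 0.07) and Fgfrl1 (-0.31 ± 0.04) fell, with adjusted p-values of 0.0397 to 0.0464. Adal did not pass (0.18 ± 0.03, adjusted p = 0.0655). Both dimmer probes of Insig1, a regulator of sterol synthesis, rose by 1.02 ± 0.12 and 0.96 ± 0.12, while its brightest probe did not pass (0.40 ± 0.15, adjusted p = 0.575). The other called probes with a symbol were dimmer probes of Klf4 (-0.38 ± 0.05), Rilpl2 (0.22 ± 0.03) and Ndrg1 (-0.57 ± 0.08). These 4 genes were named after their values were seen. Lep (0.12 ± 0.28), Adipoq (-0.06 ± 0.09), Ucp1 (0.84 ± 0.76), Fasn (0.31 ± 0.22), Scd1 (0.16 ± 0.12) and Mest (-0.34 ± 0.50) did not pass, with adjusted p-values of 0.821 or more.

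At the brightest probe of each gene, no single list member passed in limma among 489 genes in the 31 lists, 91 of them with an unadjusted p under 0.05. Insig1, both dimmer probes of which passed, belongs to the cholesterol synthesis list. Oxidative phosphorylation genes had a positive difference in 33 of 33, with a mean of 0.21 (adjusted p = 7.5e-14; adjusted p = 0.317 with an estimated correlation), and 6 passed when adjusted over the list alone. This comparison shares the EPA/DHA arrays with that against corn oil. With these split so that each used its own pair, a check chosen after the result was seen, the list means ran from 0.117 to 0.298 against low fat and from 0.229 to 0.410 against corn oil. As the splits reuse the same arrays and average to the unsplit means, they give no independent support. The 18 cholesterol synthesis genes all had positive differences, with a mean of 0.30 (adjusted p = 9.8e-12; adjusted p = 0.278 with an estimated correlation) and 7 passing when adjusted over the list alone, Msmo1 (0.66 ± 0.12) among them. Lipogenic genes had a mean of 0.41 (adjusted p = 9.2e-07; adjusted p = 0.333 with an estimated correlation), with Pcx passing when adjusted over the list alone. Fatty acid oxidation had a mean of 0.22 (adjusted p = 1.7e-06; adjusted p = 0.337 with an estimated correlation). Cell cycle genes had a mean of 0.05 (adjusted p = 0.0106; adjusted p = 0.616 with an estimated correlation). The brown adipocyte list had a mean of 0.39 (adjusted p = 0.00251; adjusted p = 0.663 with an estimated correlation), but was not called without EPA/DHA replicate 2 (adjusted p = 0.216), the array with the highest Ucp1 in WAT. Without that array or any other, the oxidative phosphorylation, cholesterol, lipogenic and fatty acid oxidation lists stayed past the threshold, their highest adjusted p-values being 2.1e-08, 4.4e-08, 1.1e-04 and 5.7e-04.

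Circadian clock genes had a mean of -0.29 (adjusted p = 0.00198; adjusted p = 0.239 with an estimated correlation). Over the list alone 7 passed as lower, including Dbp (-1.55 ± 0.53), Tef (-0.43 ± 0.17) and Nr1d2 (-0.39 ± 0.14), and 2 as higher, Arntl (0.37 ± 0.13) and Npas2 (0.06 ± 0.02). Mast cell markers had a mean of -0.17 (adjusted p = 0.00285; adjusted p = 0.42 with an estimated correlation). Weaker calls were made for endothelial markers at -0.12 (adjusted p = 0.0112; adjusted p = 0.39 with an estimated correlation), mesothelial markers at -0.16 (adjusted p = 0.0155; adjusted p = 0.617 with an estimated correlation), adipokine genes at -0.17 (adjusted p = 0.0338; adjusted p = 0.617 with an estimated correlation) and MHC class II genes at -0.10 (adjusted p = 0.0462; adjusted p = 0.734 with an estimated correlation). These 4 calls, and that of the cell cycle list, each ended without some array. The arrays were low-fat replicate 4 for endothelial markers; low-fat replicate 1 or EPA/DHA replicate 3 or 4 for mesothelial markers; low-fat replicate 2 or 3 or EPA/DHA replicate 1 or 2 for adipokine genes; low-fat replicate 3 or 4 or EPA/DHA replicate 3 for MHC class II genes; and low-fat replicate 4 or EPA/DHA replicate 2 for the cell cycle. Their adjusted p-values then reached 0.0946, 0.238, 0.243, 0.477 and 0.19. The other 19 lists had adjusted p-values from 0.0767 for macrophage markers (mean 0.28) to 0.966, and the liver score differed by -0.49 (exact permutation p = 0.486). The red blood cell score differed by 0.178 and the mast cell score by -0.174 (exact p = 0.0286, 0.294 adjusted).

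The count by limma was 13 probes, 8 higher and 5 lower, of which 4 had no symbol, and 2061 had an unadjusted p under 0.05. Without low-fat replicates 1, 2, 3 and 4 it was 2, 1, 0 and 0, and without EPA/DHA replicates 1, 3 and 4 it was 0. It was 9 without EPA/DHA replicate 2, 1 with no filter, 5 with the liver score as a covariate and 0 with 1 probe per gene. With that covariate Mcrip2, Qrsl1 and Rprml lost their calls, though their differences hardly moved (0.519, 0.36 and -0.58). None of the 4 named genes passed in every fit that left out 1 array. All 4 lost their calls without any 1 of 7 arrays, and without low-fat replicate 2 only Qrsl1 kept its call. Of genes, 4.66% did not overlap between the groups against 2.86% by chance.

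In BAT no gene passed for corn oil against low fat. Lep was 2.43 ± 0.44 higher (11.17 ± 0.72 against 8.74 ± 0.85, SD) without passing (adjusted p = 0.185), and its 4 corn-oil arrays lay above all low-fat arrays. The genes with the smallest p-values did not pass either. They were Car5b (-0.74 ± 0.11), Mmd2 (-0.73 ± 0.11), Mcam (0.60 ± 0.09), Fgf1 (0.57 ± 0.09) and Septin11 (0.53 ± 0.07), each with an adjusted p of 0.174. Nor did Mest (0.30 ± 0.10), Fasn (-0.43 ± 0.17), Ucp1 (-0.25 ± 0.15), Adipoq (-0.07 ± 0.09) and Scd1 (-0.02 ± 0.11), with adjusted p-values of 0.456 or more.

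Of the 20 adipokine and adiposity-associated genes, 17 had positive differences with a mean of 0.44 (adjusted p = 5.1e-08; adjusted p = 0.239 with an estimated correlation), and 9 passed when adjusted over the list alone, led by Lep, Sncg (1.45 ± 0.32), Npr3 (1.18 ± 0.30) and Hp (0.70 ± 0.20). Matrix genes had a mean of 0.23 (adjusted p = 2.5e-07; adjusted p = 0.452 with an estimated correlation), with 4 passing when adjusted over the list alone. Macrophage markers had a mean of 0.18 (adjusted p = 4.4e-04; adjusted p = 0.514 with an estimated correlation), fibroblast markers 0.15 (adjusted p = 0.00239; adjusted p = 0.594 with an estimated correlation), MHC class II genes 0.15 (adjusted p = 0.0021; adjusted p = 0.672 with an estimated correlation) and interferon genes 0.11 (adjusted p = 0.0126; adjusted p = 0.607 with an estimated correlation). No member of these 4 lists passed when adjusted over the list alone. The 21 skeletal muscle markers had a mean of 0.98 (adjusted p = 1.7e-04; adjusted p = 0.752 with an estimated correlation), none with an unadjusted p under 0.05 in limma. The muscle score spread from 7.89 to 11.97 over the 12 BAT arrays and did not separate the diets (10.78 ± 1.06 against 9.80 ± 0.79, SD; exact permutation p = 0.229). The Schwann cell score differed by 0.085 (exact p = 0.0286, 0.294 adjusted).

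Lower means in BAT were called for cholesterol synthesis at -0.19 (adjusted p = 3.5e-04; adjusted p = 0.476 with an estimated correlation), fatty acid oxidation at -0.12 (adjusted p = 0.00585; adjusted p = 0.452 with an estimated correlation) and triglyceride storage at -0.15 (adjusted p = 0.0104; adjusted p = 0.39 with an estimated correlation). The brown adipocyte list had a mean of -0.25 (adjusted p = 0.0122; adjusted p = 0.452 with an estimated correlation), with the potassium channel gene Kcnk3 (-0.70 ± 0.18) passing when adjusted over the list alone. Lipogenic genes had a mean of -0.20 (adjusted p = 0.0126; adjusted p = 0.616 with an estimated correlation) and insulin signalling genes of -0.15 (adjusted p = 0.0387; adjusted p = 0.333 with an estimated correlation). Over the list alone, 1 cholesterol, 1 lipogenic and 1 triglyceride gene were lower, 1 triglyceride gene was higher, and 3 oxidation genes were lower with 1 higher. Of the lower lists, cholesterol synthesis stayed past the threshold without any 1 array. The others were lost without corn-oil replicate 2 (lipogenic), corn-oil replicate 3 (triglyceride), corn-oil replicate 3 or low-fat replicate 4 (oxidation), low-fat or corn-oil replicate 3 (brown adipocyte), and low-fat replicate 1 or 3 or corn-oil replicate 1, 2 or 3 (insulin signalling), with adjusted p-values up to 0.0749, 0.0689, 0.0899, 0.148 and 0.142. Among the higher lists, fibroblast markers were lost without corn-oil replicate 3, MHC class II without corn-oil replicate 2 or low-fat replicate 4, and interferon without low-fat replicate 1 or 4 or corn-oil replicate 2 or 3, with adjusted p-values up to 0.126, 0.0931 and 0.14. Corn-oil replicate 3 had the highest muscle score of the corn-oil arrays in BAT (11.798) and the lowest Ucp1 of all BAT arrays (13.552). No list test in BAT used the muscle score as a covariate, so how far muscle in the samples made these shifts was not tested. The other 18 lists had adjusted p-values from 0.0663 for endothelial markers to 0.937. By limma 0 of 27168 probes passed and 2190 had an unadjusted p under 0.05, and 5.15% of the genes did not overlap against 2.86% by chance. Without low-fat replicate 2 the count was 2. A trended and robust prior called 11 probes and a fit over all 24 arrays 150.

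In BAT, the EPA/DHA HFD against low fat gave 1 named gene past the threshold. Sema4b, a semaphorin gene, fell by 0.47 ± 0.05 (adjusted p = 0.0432), from 10.29 ± 0.07 to 9.83 ± 0.09 (SD), while its dimmer probe, near the floor, gave 0.08 ± 0.05. The genes next in p did not pass, Tspan18 (-0.69 ± 0.09) and Cab39l (0.24 ± 0.03) with an adjusted p of 0.0582, Glrx2 (0.27 ± 0.05) and Septin11 (0.44 ± 0.07) with 0.403. Lep (0.45 ± 0.44), Fasn (-0.42 ± 0.17), Mest (0.05 ± 0.10), Ucp1 (-0.06 ± 0.15), Adipoq (0.07 ± 0.09) and Scd1 (-0.05 ± 0.11) did not pass either. Higher means were called for matrix genes at 0.18 (adjusted p = 6.0e-06; adjusted p = 0.52 with an estimated correlation), macrophage markers at 0.14 (adjusted p = 1.2e-04; adjusted p = 0.457 with an estimated correlation), fibroblast markers at 0.11 (adjusted p = 0.0192; adjusted p = 0.721 with an estimated correlation) and interferon genes at 0.09 (adjusted p = 0.0338; adjusted p = 0.663 with an estimated correlation). Lower means were called for cholesterol synthesis at -0.16 (adjusted p = 1.2e-04; adjusted p = 0.452 with an estimated correlation), lipogenic genes at -0.20 (adjusted p = 5.3e-04; adjusted p = 0.452 with an estimated correlation) and triglyceride storage at -0.12 (adjusted p = 0.0106; adjusted p = 0.39 with an estimated correlation). Of these 7 lists, triglyceride storage had 1 member passing when adjusted over the list alone and the others none.

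Matrix genes stayed called without any 1 array in that comparison. The other 6 calls ended without low-fat replicate 2 (cholesterol synthesis), EPA/DHA replicate 3 (lipogenic), EPA/DHA replicate 2 (triglyceride), EPA/DHA replicate 4 (macrophage), low-fat replicate 3 or 4 or EPA/DHA replicate 4 (fibroblast), and low-fat replicate 1 or 4 or EPA/DHA replicate 2, 3 or 4 (interferon). Adjusted p-values then reached 0.0596, 0.133, 0.0532, 0.0549, 0.287 and 0.159. The other 24 lists ran from 0.0699 for insulin signalling to 0.942. The muscle score was 10.12 ± 1.78 (SD) on EPA/DHA (exact permutation p = 0.714 against low fat). By limma 2 probes passed, both lower and 1 of them without a symbol, against 1371 with an unadjusted p under 0.05. A fit over all 24 arrays called 25 probes, none of them these 2, and a trended and robust prior or 1 probe per gene called 0. Sema4b passed without EPA/DHA replicate 2 and lost its call without any 1 of the other 7 arrays. The count was 1 without EPA/DHA replicate 1 and 0 without EPA/DHA replicate 3 or 4 or any 1 low-fat array, and 2.63% of the genes did not overlap against 2.86% by chance.

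For the EPA/DHA against the corn-oil HFD in BAT, Lep had a difference of -1.98 ± 0.44 that did not pass (adjusted p = 0.612). The adipokine and adiposity list, which was higher on corn oil, was lower here, with a mean of -0.38 (adjusted p = 1.4e-06; adjusted p = 0.239 with an estimated correlation). When adjusted over the list alone 6 genes passed, including Sncg (-1.62 ± 0.32), Lep and Npr3 (-1.24 ± 0.30). Both comparisons share the corn-oil arrays, which alone makes them mirror each other. With these arrays split so that each comparison used its own pair, a check chosen after the result was seen, the list means ran from 0.337 to 0.536 and from -0.475 to -0.277 over the 6 splits. The splits reuse the same arrays and average to the unsplit means, so they give no independent support. The genes with the smallest p-values, Plin4 (-0.61 ± 0.11), Nbdy (-0.37 ± 0.07), Sema4b (-0.30 ± 0.05), Glrx2 (0.25 ± 0.05) and Il6st (0.25 ± 0.05), each had an adjusted p of 0.574. Mest (-0.26 ± 0.10), Ucp1 (0.18 ± 0.15), Adipoq (0.14 ± 0.09), Fasn (0.00 ± 0.17) and Scd1 (-0.03 ± 0.11) had an adjusted p of 0.999.

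Lower means were also called for MHC class II genes at -0.15 (adjusted p = 6.8e-04; adjusted p = 0.617 with an estimated correlation), skeletal muscle markers at -0.66 (adjusted p = 0.00768; adjusted p = 0.836 with an estimated correlation), endothelial markers at -0.13 (adjusted p = 0.00943; adjusted p = 0.452 with an estimated correlation) and heat shock genes at -0.28 (adjusted p = 0.0361; adjusted p = 0.741 with an estimated correlation). A higher mean was called for liver markers at 0.18 (adjusted p = 0.0445; adjusted p = 0.721 with an estimated correlation). No member of these 5 lists passed when adjusted over the list alone. The calls ended without corn-oil replicate 2 (MHC class II), EPA/DHA replicate 1 or 3 or corn-oil replicate 3 or 4 (muscle), corn-oil replicate 2 or EPA/DHA replicate 4 (endothelial), corn-oil replicate 1 or 4 or EPA/DHA replicate 2 or 4 (heat shock), and corn-oil replicate 1, 3 or 4 or EPA/DHA replicate 2 or 4 (liver). Their adjusted p-values then reached 0.0948, 0.744, 0.101, 0.949 and 0.788, and the muscle list turned to 0.08 without EPA/DHA replicate 3. The other 25 lists ran from 0.0657 for Schwann cell markers to 0.908. By limma 0 probes passed, 1264 had an unadjusted p under 0.05, a fit over all 24 arrays called 6, and 3.71% of the genes did not overlap against 2.86% by chance.

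**Figure D2:**
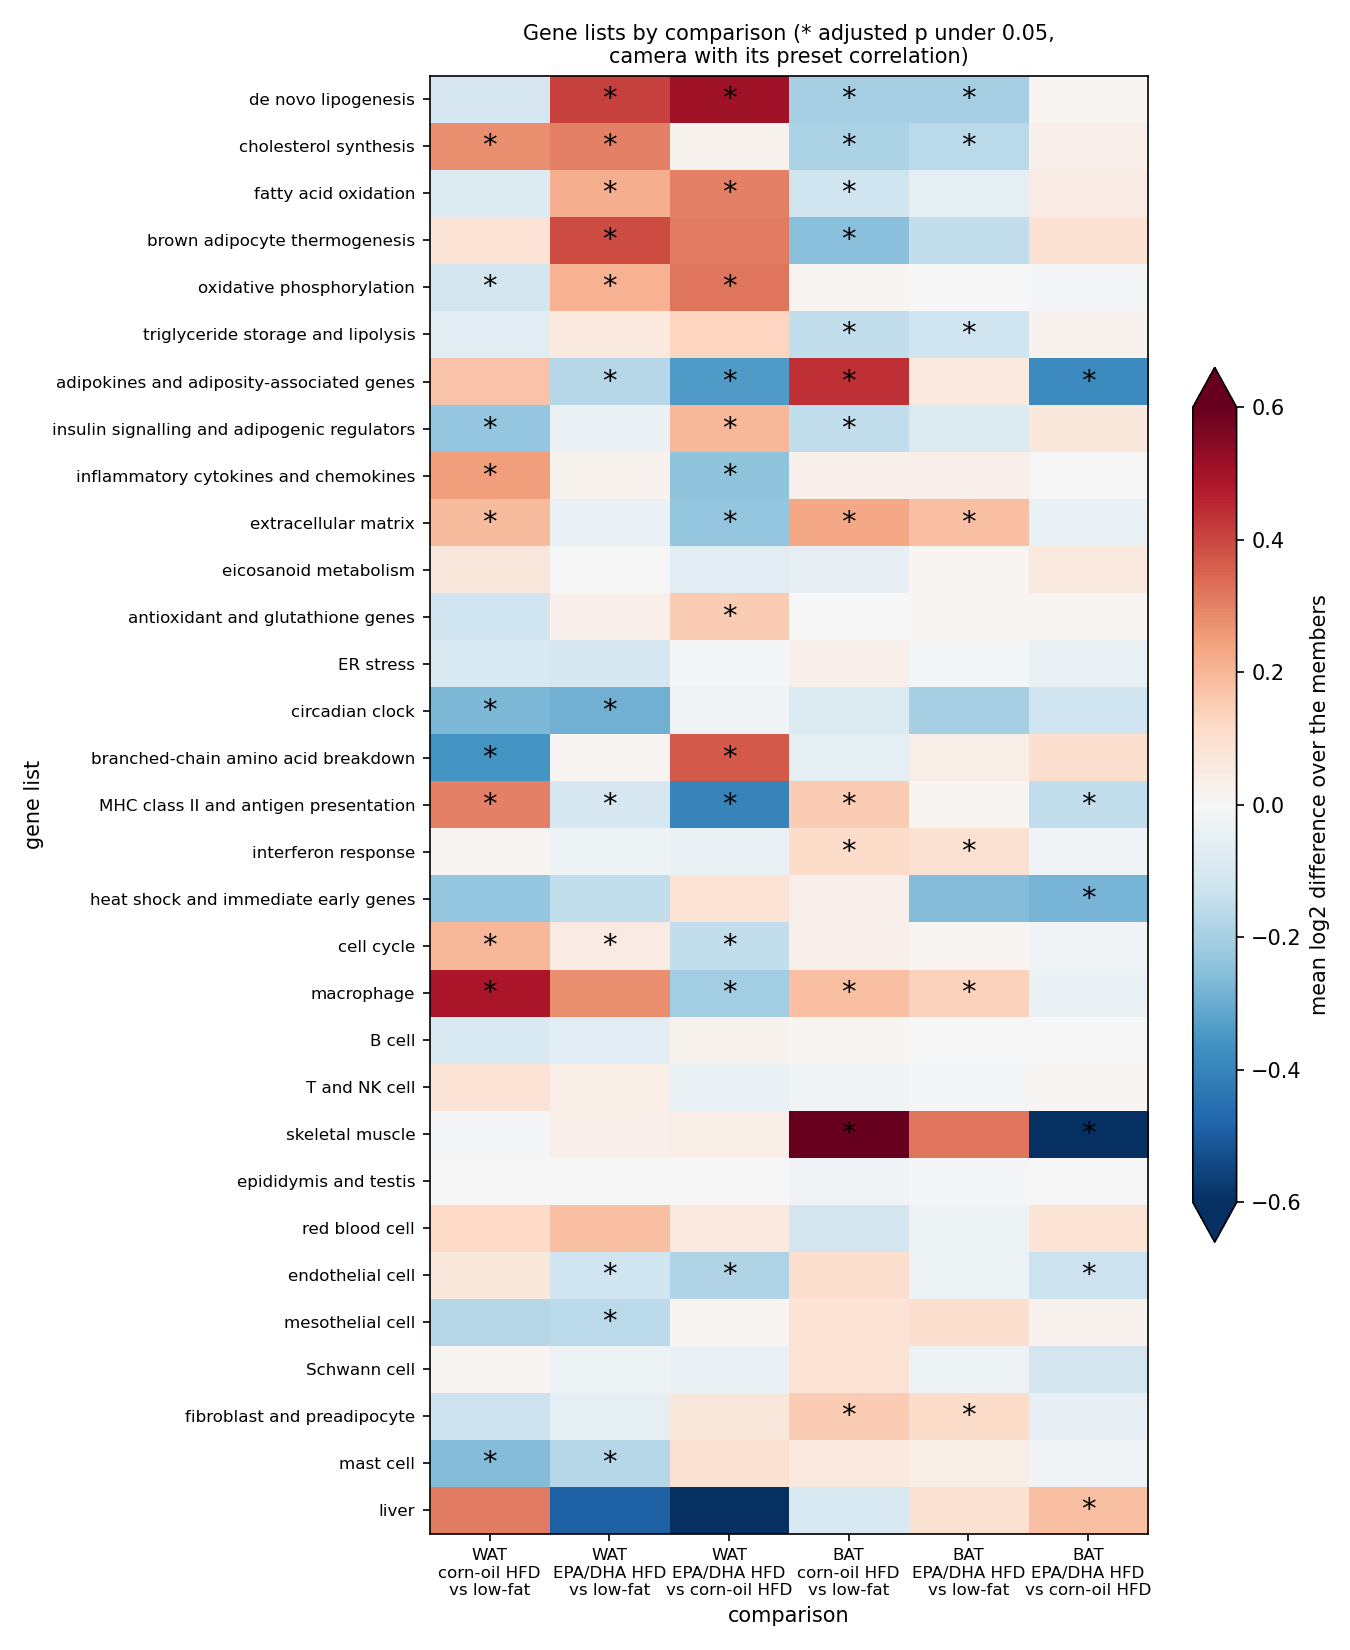
Mean log2 difference over the members of 31 gene lists (vertical axis) in 6 comparisons (horizontal axis), with a star for an adjusted p under 0.05 by camera with its preset correlation. Oxidative phosphorylation has means of 0.21 and 0.32 for EPA/DHA against low fat and against corn oil in WAT, and the adipokine list in BAT goes from 0.44 for corn oil against low fat to -0.38 for EPA/DHA against corn oil, each of these 2 pairs of comparisons sharing 1 group of arrays; no call holds with an estimated correlation, and the color scale ends at 0.6.

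Across the 6 comparisons camera called 62 of the 186 list tests, 30 higher and 32 lower. With an estimated correlation it called 0, the lowest adjusted p being 0.239, and 22 tests had an unadjusted p under 0.05. Fry called 13 for a shift in 1 direction and 40 for a change in either. The lists never called were eicosanoid metabolism, ER stress, B cells, T and NK cells, epididymis and testis, red blood cells and Schwann cells, with lowest adjusted p-values of 0.589, 0.0979, 0.264, 0.412, 0.733, 0.118 and 0.0657. The median, the mean and the test differed in sign in 17 tests, none of them called. In WAT these were interferon and Schwann for corn oil against low fat, inflammatory for EPA/DHA against low fat, and circadian, muscle and fibroblast for EPA/DHA against corn oil. In BAT they were eicosanoid, antioxidant, ER stress and mesothelial for corn oil against low fat, oxidation, antioxidant, branched-chain, cell cycle and Schwann for EPA/DHA against low fat, and lipogenic and ER stress for EPA/DHA against corn oil.

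For corn oil against low fat, the diet effect differed between the tissues in 93 genes. The effect on Ubd was 2.41 ± 0.22 larger in WAT than in BAT (adjusted p = 9.0e-06), and that on Tph2 2.60 ± 0.34 larger. In BAT both genes lay near the floor, Ubd at 7.38 ± 0.06 on corn oil and Tph2 at 7.18 ± 0.09 (SD). Septin9 (1.35 ± 0.18), Stambpl1 (0.96 ± 0.11) and Kcnj14 (0.51 ± 0.06) followed. In all 149 probes passed, 99 with a more positive effect in WAT and 50 with a more negative one. For EPA/DHA against corn oil 58 probes passed, 15 and 43, a count for which regrouping the arrays did not exclude chance, led by Ubd (-2.36 ± 0.22), Ear3 (-1.15 ± 0.15), Ccn5 (-0.86 ± 0.11), Stambpl1 (-0.81 ± 0.11) and Shroom2 (-0.43 ± 0.06). A dimmer Shroom2 probe near the floor gave 0.00 ± 0.04. For EPA/DHA against low fat the 3 probes past the threshold were Tspan18 (0.77 ± 0.12) and both dimmer probes of Insig1 (1.87 ± 0.20 and 1.61 ± 0.17, adjusted p = 1.7e-04), the latter named after their values were seen. Its brightest probe did not pass (0.41 ± 0.22, adjusted p = 0.813).

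The interaction count for corn oil against low fat was 84 without BAT corn-oil replicate 1 or replicate 3, 87 and 55 without WAT low-fat replicates 1 and 4, and 86 and 81 without WAT corn-oil replicates 3 and 4. It was 88 without the 3 arrays that stood apart. For EPA/DHA against corn oil it was 34 without BAT corn-oil replicate 1 and 89 without those 3 arrays. The 5 named genes of each passed without any 1 array. For EPA/DHA against low fat the count was 5 without BAT EPA/DHA replicate 2, WAT EPA/DHA replicate 3 or WAT low-fat replicate 3, and Tspan18 lost its call without BAT EPA/DHA replicate 3 or 4, BAT low-fat replicate 1 or 3, or WAT low-fat replicate 2 (adjusted p up to 0.0659). Of genes called in WAT for EPA/DHA against corn oil, 216 of 300 (72.0%) had the same sign in BAT, more than in most of the 70 relabelings of the BAT arrays but short of the threshold (exact p = 0.0571). For corn oil against low fat the share was 290 of 492 (58.9%, exact p = 0.457), and for EPA/DHA against low fat 3 of 4 (exact p = 0.714).

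**Figure D3:**
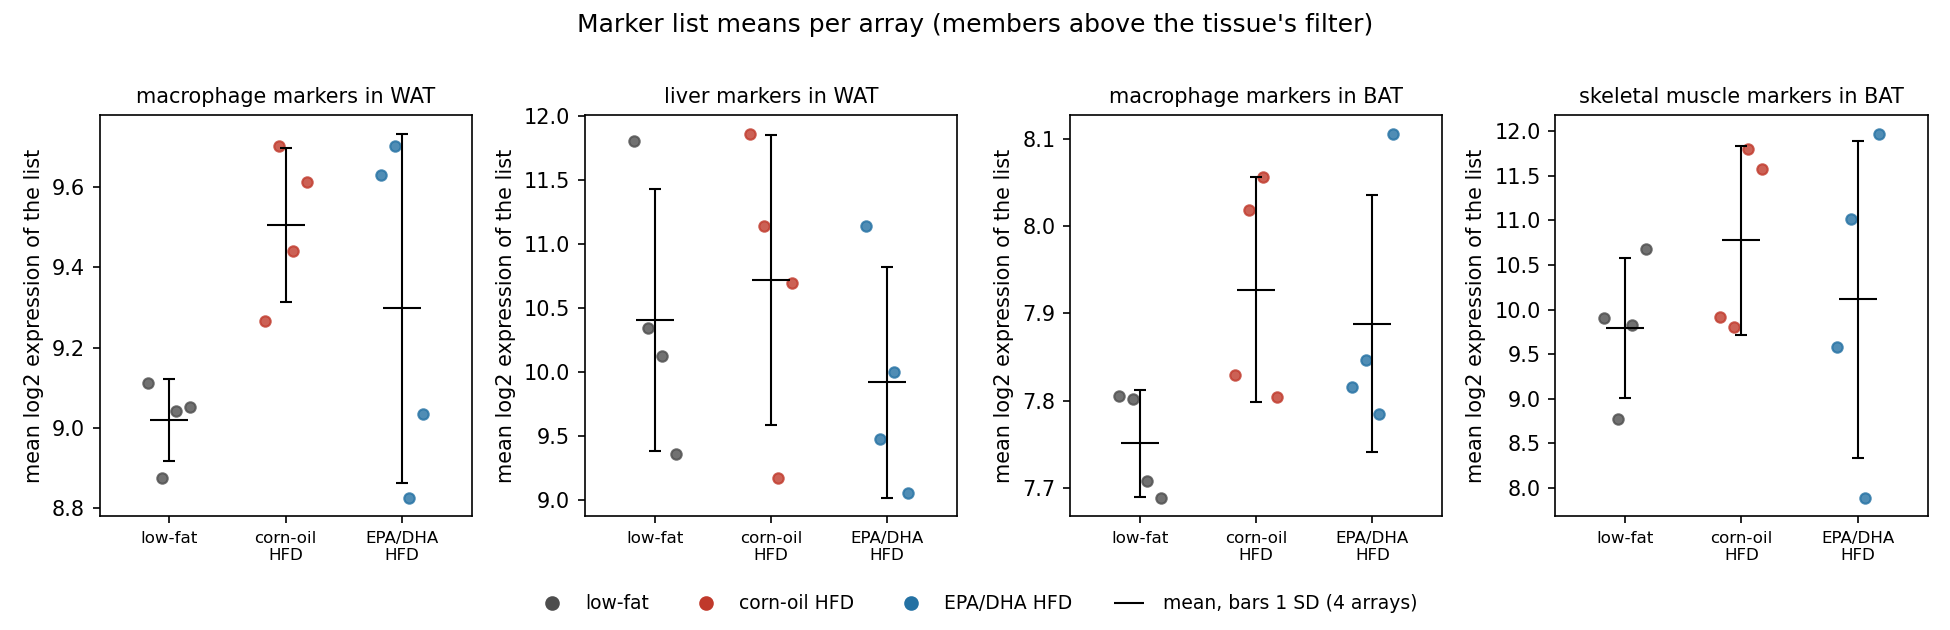
Mean log2 expression of marker lists per array on the 3 diets, for macrophage and liver markers in WAT and macrophage and skeletal muscle markers in BAT, with 1 point per array, the mean and 1 SD. In WAT all corn-oil arrays lie above all low-fat arrays for macrophage markers, while liver markers spread from 9.05 to 11.86 and muscle markers in BAT from 7.89 to 11.97 within and across diets; the vertical axes do not start at 0.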

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

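The tests of the liver transcripts, the brown share over 66 genes and how it was read, the reading of the small counts in BAT beside the share of genes that did not overlap, and the fits that left out doubted arrays or used a liver or muscle score were chosen after the result was seen.

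The higher macrophage markers in WAT on the corn-oil HFD than on the low-fat diet were weighed against a lower share of adipocyte RNA and against lymph node tissue. A lower adipocyte share would raise every other cell type alike, but the macrophage score minus the endothelial and fibroblast score was 0.518 higher (0.310 ± 0.219 against -0.208 ± 0.150, SD, n = 4; exact permutation p = 0.0286), which argues against it. Lymph node tissue would raise lymphocyte markers as much, but the macrophage score minus the B, T and NK cell score was 0.493 higher (2.036 ± 0.149 against 1.544 ± 0.075; exact permutation p = 0.0286). That p is the smallest possible for groups of 4. A higher share of macrophages and a higher expression per macrophage, both possible effects of the diet, stayed open.

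Ucp1 stood far above the other 3 arrays of its group in WAT EPA/DHA replicate 2, at 10.632 (others 7.18 to 7.76), and in WAT corn-oil replicate 4, at 9.376 (7.11 to 7.18). Brown tissue in these samples could raise Zic1, a gene of classical brown fat, but Zic1 was 7.044 and 7.096, within the 7.003 to 7.112 of the other 10 WAT arrays (BAT 7.505 to 7.893). In EPA/DHA replicate 2 the share given by Cidea (23.3%) predicted a Zic1 of 7.215, so the bound written before against brown tissue was met, but this was not taken as decisive because the shares given by Ucp1 (8.3%) and by the median of 66 genes high in BAT (9.01%, quartiles 5.89 to 14.03) predicted 7.112 and 7.117, at the edge of that range and near the floor. In corn-oil replicate 4 the median share was 0.75% (quartiles -1.25 to 2.11), below the 2.9% of Ucp1 and Cidea and within the -2.15% to 2.41% of the other 10 arrays, and Zic1 was predicted at 7.057 to 7.073. The median share of 9.01% in EPA/DHA replicate 2 lay above the -2.15% to 2.41% of the other 10 arrays. Zic1 lay near the floor and its predicted rises were small, so it cannot tell brown tissue from browning of white fat in either array. In corn-oil replicate 4 the 66 genes give brown tissue no support.

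Liver transcripts varied widely in WAT, the liver score running from 9.048 to 11.861. The probes of the abundant liver genes Alb (7.02 to 7.13), Fgb (6.99 to 7.19) and Fabp1 (7.02 to 7.10) stayed at the floor. Within these narrow ranges Alb correlated with the liver score at 0.649, Fgb at -0.057 and Fabp1 at 0.087. The 9 measured liver markers rose and fell together over the 12 arrays, with a median pairwise correlation of 0.925, and 108 of 324 varying genes correlated above 0.95 with the score, 102 of them outside the list. Outside the list, the liver genes Fgg, Cps1, Hamp, Gnmt and Arg1 correlated with the score at 0.994, 0.980, 0.990, 0.996 and 0.985. Fgg ran from 7.745 to 10.923 in WAT while Fgb stayed flat. These values go with liver RNA, but liver RNA would bring Alb, Fgb and Fabp1 too. As these 3 probes were not tested, liver RNA with 3 failed probes and a source other than liver cannot be told apart. The diet as the source of the spread was argued against, since the largest difference between diet means was 0.801 (smallest exact permutation p = 0.314) and the smallest range within a diet 2.094. No other biological explanation was tested.

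The arrays were regrouped to see how often another grouping gave as large a count. In WAT the real grouping was the 1 split of 35 with as many for corn oil against low fat (797 probes, highest other split 0). The same held for EPA/DHA against corn oil (477, highest other 0). The real grouping was also the 1 of 35 for EPA/DHA against low fat in WAT (13, highest other 1), where 4.66% of the genes did not overlap against 2.86% by chance. For corn oil against low fat in BAT, where 0 probes passed, 5.15% of the genes did not overlap. As 1 of 35 is the smallest share that the splits can give, chance was made rare and not ruled out for these counts in WAT. The count of 13 was also small. That count fell to 0 without any 1 of 5 arrays and with 1 probe per gene. For WAT against BAT (11050, highest other 496) the share was again 1 of 35, with the same limit. In BAT the test decided nothing for corn oil against low fat (0, highest other 6) and EPA/DHA against corn oil (0, highest other 223), since all 35 splits reach a count of 0. For EPA/DHA against low fat in BAT (2, highest other 1) the real grouping was again 1 of 35, but 2.63% of the genes did not overlap against 2.86% by chance, so chance was left open. How far the share that did not overlap varies over the splits was not computed, so it decides none of these counts. The split with 223 parted BAT arrays with muscle scores of 7.886 to 9.914 from those of 11.017 to 11.974, a structure of the samples that is not the diet. For the interactions, the bound set before (fewer than 5% of the splits) was met for corn oil against low fat (149, highest other 240, 2 of 100 splits) and EPA/DHA against low fat (3, highest other 3, 2 of 100). As 1 regrouping gave more in the former and 1 as many in the latter, chance was made rare there and not ruled out. The bound was not met for EPA/DHA against corn oil (58, highest other 275, 10 of 100), so chance was left open. What set apart the arrays in the split with 275 was not examined.

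Diet effects that differed between the tissues by a test of the difference covered 149 probes for corn oil against low fat, among them Ubd (2.414), Tph2 (2.596), Septin9 (1.350), Stambpl1 (0.961) and Kcnj14 (0.512). They covered 3 probes for EPA/DHA against low fat, with Tspan18 at 0.770. For EPA/DHA against corn oil they covered 58 probes, among them Ubd (-2.357), Ear3 (-1.151), Ccn5 (-0.856), Stambpl1 (-0.807) and Shroom2 (-0.431).

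Single arrays far from the other 3 of their group were found in 20 of 353 groups tested (5.7%), and chance gives about 1 in 20. In WAT low-fat replicate 1 these were Slpi at 12.679 (others 11.16 to 11.33), Ucp1 at 8.023 (7.09 to 7.21), Acot11 at 7.486 (7.18 to 7.20) and Adipoq at 14.137 (14.35 to 14.39). In WAT corn-oil arrays they were H2-DMb1 at 9.886 (9.31 to 9.37) and Cox4i1 at 13.390 (13.46 to 13.47) in replicate 4, Ndufa2 at 11.970 (12.17 to 12.20) and Ccn5 at 7.835 (8.21 to 8.28) in replicate 2, Kcnj14 at 7.638 (7.74 to 7.76) in replicate 1 and the mesothelial score at 7.871 (8.05 to 8.08) in replicate 3. In WAT EPA/DHA arrays they were Adipoq at 14.420 (14.17 to 14.20) in replicate 4 and the skeletal muscle score at 7.642 (7.79 to 7.82) in replicate 1. In BAT they were Cox7a1 at 14.459 (14.07 or less) and Fabp3 at 12.603 (13.30 to 13.43) in low-fat replicate 2, the mesothelial score at 7.771 in low-fat replicate 4 (7.79 in the others), Tspan18 at 8.795 (8.39 to 8.45) in EPA/DHA replicate 2, Ear3 at 7.628 (7.22 to 7.29) in EPA/DHA replicate 4 and Il6st at 7.880 (7.96 to 7.98) in corn-oil replicate 3.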

How the results depend on the processing

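Fits without doubted arrays and with a liver or muscle score as a covariate were chosen after the data were seen. For named genes 2070 values kept their direction and side of the threshold, 469 fell below it, 8 rose above it and 30 changed sign; for lists these were 852, 139, 0 and 1; of counts 177 stayed within 1.5 times and 62 did not. Leaving out 1 array gave 266 to 602 probes for WAT corn oil against low fat (797), 0 to 9 for EPA/DHA against low fat (13) and 175 to 465 for EPA/DHA against corn oil (477). In BAT it gave 0 to 2 for corn oil against low fat (0) and 0 to 3 for EPA/DHA against low fat (2), and for the interactions 55 to 149 (149), 2 to 5 (3) and 34 to 74 (58). Without the 2 WAT arrays with raised Ucp1 the WAT counts were 380 and 299 for the comparisons with corn oil, and without 3 doubted arrays the interactions with corn oil gave 88 and 89. The liver covariate gave 5 (EPA/DHA against low fat) and 300 (EPA/DHA against corn oil) in WAT, and the muscle covariate 1 for both comparisons with low fat in BAT. No filter gave 1 for WAT EPA/DHA against low fat. A fit over all 24 arrays gave 7 there, and 150, 25 and 6 in BAT; a trended robust prior gave 11 and 0 for BAT corn oil and EPA/DHA against low fat. With 1 probe per gene, which tests fewer, the counts were 0 for EPA/DHA against low fat in both tissues, 1 for its interaction and 6331 for WAT against BAT. Camera with an estimated correlation called 0 lists (62).

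The genes that changed sign had not passed. In WAT, leaving out 1 array gave, for corn oil against low fat, Fasn -0.285 to 0.008 and Ucp1 -0.211 to 0.573; for EPA/DHA against low fat, Lep -0.060 to 0.325 and Mest -0.723 to 0.031; and for EPA/DHA against corn oil, Adipoq -0.059 to 0.060, Scd1 -0.135 to 0.064 and Ucp1 -0.319 to 1.054. In BAT it gave, for corn oil against low fat, Scd1 -0.081 to 0.060. It gave Scd1 -0.112 to 0.040 and Ucp1 -0.168 to 0.064 for EPA/DHA against low fat, and for EPA/DHA against corn oil Fasn -0.090 to 0.135, Scd1 -0.107 to 0.058 and the skeletal muscle list, which had been called, -1.280 to 0.083. Without the 2 WAT arrays with raised Ucp1, Ucp1 was -0.211 for corn oil against low fat and Scd1 0.125 for EPA/DHA against corn oil, and with the liver covariate Adipoq was -0.026 there. With the muscle covariate in BAT, Adipoq and Scd1 for corn oil against low fat were 0.010 and 0.024, and Fasn for EPA/DHA against corn oil was -0.003 (-0.006 with array weights). The cause was not tested.

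With the replicate number as a block within a tissue, counts were 500 (797), 5 (13) and 394 (477) in WAT. They were 0 for EPA/DHA against low fat in BAT (2) and 66 for the lists (62). Over both tissues the block was diet and replicate number together. Counts were then 56 (149), 4 (3) and 18 (58) for the interactions and 10260 (11050) for WAT against BAT. The numbers showed no pairing of the arrays, which does not exclude the same mouse in 2 tissues, as its tissues need not deviate alike. Deviations of arrays with the same number correlated at -0.27 to 0.55 within WAT, -0.36 to 0.44 within BAT and -0.21 to 0.07 between tissues, and 4 of 12, 3 of 12 and 3 of 24 arrays correlated best with their own number. Signal over background limited dim probes, as values near the floor of about 7 can hide a change.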
